A study of Rattus norvegicus with 6 samples.

How the data were processed

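The samples were 6 small RNA libraries of RSC96 cells after 48 h of treatment, 3 in high and 3 in low glucose, grouped and numbered by their titles. The authors' files hold raw counts, per the file headers: reads per distinct sequence and hairpin, with the sequence, its length, its place in the hairpin and its mismatches. The submitters' processing notes name cutadapt 1.9.3 and Novoalign 3.02.12 without their roles. Tested on the deposited counts, listed sequences are 16 to 40 nt long, have at least 2 reads and carry at most 1 mismatch. The reads of a sequence listed under several hairpins add up to its total within rounding. For thinned counts they were divided evenly among these hairpins. The hairpins are 281 annotated and 540 predicted ones. The genome build and the hairpin database release are not given in the sources used here, so no genomic coordinates are given, and places are positions in the hairpin counted from 1 at its 5′ end. Of the annotated hairpin names, 258 were found in a table of rat genes for the GRCr8 assembly, which was used only for names. Predicted hairpins are referred to by the chromosome and number in their names.

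From these files, counts were summed per mature arm. Hairpins that are copies of one miRNA were joined, 41 hairpin sequences listed under several names were each taken as 1, and a sequence was given to the 5p or 3p arm by the side of the hairpin midpoint on which its centre lies. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 was used for this, and matplotlib 3.10.9 for the figures. The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood test with TMM scaling, filterByExpr with its default minimum count of 10, robust dispersions and Benjamini-Hochberg adjustment at 0.05. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The standard error of a log2 fold change is the fold change divided by the square root of its F statistic.

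Beside the main test, 29 lists of miRNA families, genomic clusters, functions and cell type markers were fixed, of which 19 had 3 or more tested members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Library measures were compared by exact two-sided permutation tests, for which 3 against 3 libraries give 10 splits and no p under 0.1. Detection at equal depth used 20 seeded draws of 114497 reads per library, with the minimum of 2 reads per sequence applied again. The groups, tests, lists and alternatives, and the rule for the miRNAs to name, were chosen before the data were examined. That rule selected, as the named miRNAs, the 10 called miRNAs with the largest rise and the 10 with the largest fall among those with separate groups and a mean of 50 or more counts in a group, the 10 most abundant, and in each tested list the 2 most abundant and 2 most changed members. Not all of them are described in the text. miR-122-5p, miR-192-5p and miR-183-5p are named as members of lists too small to test, and let-7a-3p, let-7c-3p and miRNAs named only in the closing section were chosen after their values were seen. Alternatives were other scalings, filters and tests, a replicate block, thinned counts, fewer miRNAs or sequences, and fits without each library in turn. Those added after the data were seen were annotated hairpins only, exact alignments only, a correction for GC content, and joined arms, in which arms with 50% or more of their counts in sequences listed under another arm were summed with it, leaving 824 of the 932.

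Counts were simulated for 932 miRNAs with the depths of this comparison, of which 200 were changed and 296 were tested. The fit recovered 29 of 36 tested miRNAs changed 4-fold and 7 of 26 changed 2-fold. Of its 40 calls 4 were false, or 10%, a share above the threshold set for the adjusted p. In the data 190 of 297 tested miRNAs were called, a larger share than was changed in the simulation. The simulation thus does not test the fit where most miRNAs change. Being made per miRNA, it also does not test the minimum of 2 reads per sequence. Depth limits the low glucose group most, at 114615 to 148143 counts per library. The 49 higher miRNAs with a low glucose mean of 3 or fewer counts have imprecise fold changes. Where a group had 1 to 3 counts in total, a ratio with an exact 95% binomial interval is given, and a group listed at 0 gets no fold, since single-read sequences are not listed. Reads carry no molecular identifiers here, so intervals cover counting error only. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom from 5.31 to 196, and none was taken as a repeat of another. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. miR-29b-3p is called uncertain because most of its counts were shared with another miRNA.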

Results

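Small RNA was sequenced from RSC96, a rat Schwann cell line, after 48 h in high or low glucose, with 3 libraries in each group. Schwann cells are the glia that wrap the axons of peripheral nerves, and high glucose in culture is a common model of diabetic nerve damage. The series title concerns the exosomes of Schwann cells, small vesicles that cells release, and the labels do not say whether a library was made from vesicles or from whole cells. The extraction text in the labels names another tissue, the retina, while the cell line and nerve are given in the sample characteristics. The low glucose libraries served as the controls. The high glucose libraries held 963706, 1278405 and 1354456 counts and the low glucose libraries 123716, 148143 and 114615, a 9.31-fold difference between the group means. The counts fell on 932 mature miRNA arms, 362 from annotated hairpins and 570 from hairpins that the authors had predicted, and 297 of these, 198 annotated and 99 predicted, had enough counts to be tested.

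The comparison of high with low glucose asked which miRNAs changed with the glucose level. The let-7 miRNAs let-7c-5p and let-7b-5p, known as repressors of growth-promoting genes, were among the most abundant miRNAs that rose in high glucose. let-7c-5p went from 15287 ± 1125 CPM (counts scaled to library size) in low glucose to 121716 ± 21201 CPM in high glucose (SD, n = 3), a 7.96-fold difference. miR-10b-5p and miR-10a-5p, which are encoded within the Hox gene clusters, rose 4.92-fold and 4.39-fold. miR-21-5p, a miRNA often raised in injured tissue and the most abundant one in both groups, fell from 420781 ± 51108 CPM in low glucose to 173417 ± 34971 CPM in high glucose (SD, n = 3), and was 2.43-fold lower. miR-451-5p, a miRNA of red blood cells, was 8.53-fold lower in high glucose, and miR-184-3p was 8.24-fold lower. Mean raw counts of both were near-equal, at 349 in low and 355 in high glucose for miR-451-5p, and 516 and 540 for miR-184-3p. These 2 folds thus rest on the scaling to library size, with total counts that differed 9.31-fold.

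In all, 123 miRNAs were higher and 67 lower in high glucose by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and 107 did not pass. Of the annotated miRNAs, 77 were higher and 51 lower. Some reads were counted under several arms: 25 of the 46 higher predicted arms, 4 of the higher annotated arms, let-7a-3p and let-7c-3p among them, and 3 of the lower predicted arms had over 50% of their counts in sequences shared with another arm. With such arms joined, 96 of 253 were higher and 63 lower, and 60.4% of the calls were higher. Of the 297 tested miRNAs, called or not, 136 had all high glucose libraries above and 77 all below the low glucose ones, where chance separates 10% in either direction. The higher miRNAs included 22 that were listed at 0 in all low glucose libraries, and 1 lower one was listed at 0 in all high glucose libraries. With upper quartile scaling, which moved the median log2 fold change of the tested miRNAs by -0.58, 49.5% of the calls were higher in place of 64.7%, and the counts were 91 higher and 93 lower. After all libraries were thinned to the smallest one, 66 of 167 tested miRNAs were higher and 64 lower, a share of 50.8% higher. Without high glucose replicate 2, with 203 miRNAs tested, 79 were higher, and without low glucose replicate 2, 41 were lower.

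**Figure D1:**
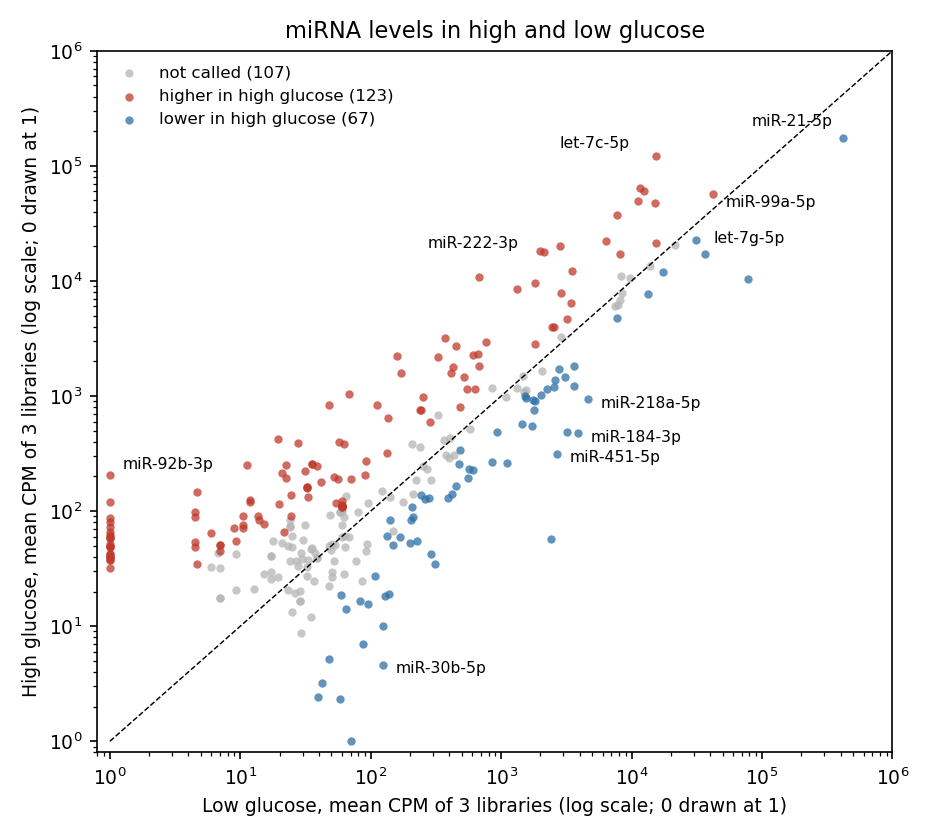
Mean CPM of each of the 297 tested miRNAs in the 3 high glucose libraries (vertical, log scale) against the 3 low glucose libraries (horizontal, log scale), with a dashed line where both are equal and miRNAs listed at 0 drawn at 1. The 123 miRNAs higher in high glucose lie above the line, let-7c-5p among them, and the 67 lower ones lie below it, miR-21-5p among them.

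The most abundant miRNAs carried most of the counts. Among the 10 with the highest mean CPM, let-7c-5p had a log2 fold change of 2.99 (SE 0.18, edgeR adjusted p = 2.54e-05), let-7b-5p 2.48 (SE 0.20), miR-10b-5p 2.30 (SE 0.19), miR-10a-5p 2.13 (SE 0.18) and miR-30d-5p 1.66 (SE 0.15). On the log2 scale miR-21-5p fell by 1.28 (SE 0.19, edgeR adjusted p = 0.000948) and let-7g-5p fell by 1.09 (SE 0.17). miR-99a-5p was at 56844 ± 8639 CPM in high glucose and 41917 ± 2453 CPM in low glucose (SD, n = 3), a log2 fold change of 0.44 (edgeR adjusted p = 0.0407) that turned to -0.14 with upper quartile scaling. miR-146b-5p, linked to inflammation, had a log2 fold change of -0.46 (edgeR adjusted p = 0.0471), and 0.078 when only its most abundant sequence was counted. The calls of miR-99a-5p and miR-146b-5p were lost without high glucose replicate 2, low glucose replicate 1 and low glucose replicate 3, that of miR-99a-5p also without high glucose replicate 3, and that of miR-146b-5p also without high glucose replicate 1 and low glucose replicate 2. The predicted hairpin numbered 34122 on chromosome 7 also belonged to this group, at 10395 ± 2616 CPM in high and 78707 ± 17463 CPM in low glucose (SD, n = 3). Only 4.60% of its counts matched its hairpin without a mismatch, so what RNA it stands for is uncertain.

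The main sequence of let-7c-5p, TGAGGTAGTAGGTTGTATGGTT, lies at positions 14 to 35 of the 95 nt let-7c-2 hairpin and made up 76.9% ± 0.762 of the let-7c-5p counts in high glucose and 74.0% ± 0.751 in low glucose (SD, n = 3). The main sequence of miR-21-5p, TAGCTTATCAGACTGATGTTGAC, lies at positions 18 to 40 of its 92 nt hairpin and made up 81.1% ± 3.45 and 83.9% ± 1.33 of its counts in the same order. For miR-10b-5p the main sequence, TACCCTGTAGAACCGAATTTGT at positions 26 to 47 of a 109 nt hairpin, made up 81.8% ± 0.989 in high and 60.2% ± 2.61 in low glucose.

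**Figure D2:**
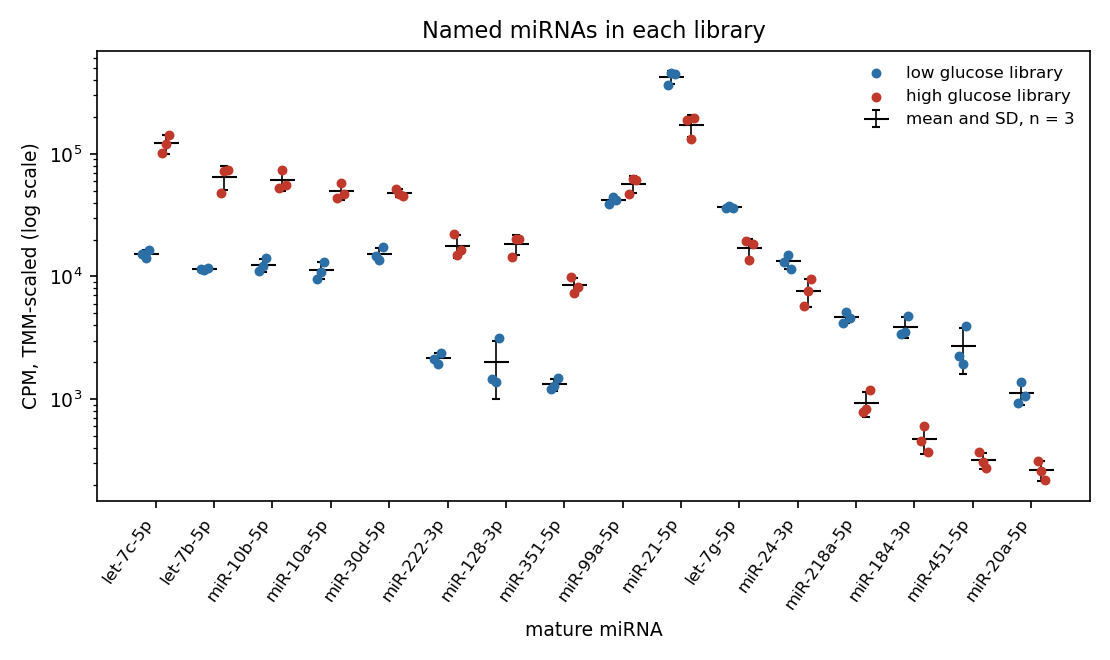
CPM of 16 named miRNAs (horizontal) in each library on a log scale (vertical), with red points for high and blue points for low glucose libraries and black bars for the mean and SD of 3 libraries. The high glucose points of let-7c-5p lie above its low glucose points, and those of miR-21-5p and miR-451-5p lie below.

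Among called miRNAs with a mean of 50 or more counts in a group, the 10 largest rises by fitted fold change were in miRNAs that the low glucose libraries did not list at all. This ranking depends on the value fitted for a listed 0. miR-92b-3p stood at 205 ± 77.1 CPM in high glucose (SD, n = 3), a level that would give 22.9 to 30.6 reads in a low glucose library, and was listed at 0 in all 3. miR-129-5p stood at 121 ± 40.001 CPM and miR-872-3p at 87.5 ± 22.5 CPM in high glucose (SD, n = 3), and both were also listed at 0 in low glucose. The same held for miR-543-3p at 59.4 ± 11.2 CPM, miR-450b-3p at 58.9 ± 24.2 CPM and miR-10a-3p at 58.9 ± 34.1 CPM (SD, n = 3), and for 4 predicted hairpins. In a low glucose library these 3 levels would give only 6.63 to 8.87, 6.58 to 8.80 and 6.57 to 8.79 reads. At so few reads, sequences seen once could leave a listed 0. No fold is given for these 10, because sequences seen in a single read are not listed and a listed 0 sets no floor. In the thinned counts miR-92b-3p still had 21.7 counts per high glucose library on average, and miR-543-3p 3.67.

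Of the 10 largest falls under the same minimum, 6 were annotated miRNAs. miR-184-3p dropped from 3901 ± 757 to 473 ± 115 CPM, and miR-451-5p from 2700 ± 1085 to 316 ± 49.4 CPM (SD, n = 3). Raw counts of both were near-equal in the groups, so these are falls in scaled counts only. miR-218a-5p was 4.96-fold lower (edgeR adjusted p = 7.64e-05), miR-20a-5p, a member of the growth-linked miR-17~92 cluster, 4.23-fold lower, and miR-652-3p 6.70-fold lower. miR-455-5p was 3.84-fold lower (edgeR adjusted p = 0.0332), and its call was lost without high glucose replicate 2 and without each of the 3 low glucose libraries. The other 4 were predicted hairpins, of which the one numbered 11530 on chromosome 13 went from 2410 ± 399 CPM in low to 57.7 ± 6.56 CPM in high glucose (SD, n = 3), with 12.7% of its counts matching without a mismatch.

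The counts of called members in each list stand beside 123 higher and 67 lower among all 297 tested miRNAs. Among families, let-7 and miR-98 had 10 members higher and 2 lower of 14 tested, and the same 10 and 2 adjusted over the list alone. Besides let-7c-5p and let-7b-5p, let-7d-3p was 13.9-fold higher, while let-7g-5p was lower, and upper quartile scaling gave 9 higher and 3 lower. let-7a-3p and let-7c-3p, counted among the 10, shared 100% and 98.6% of their counts with another arm, so they are largely the same reads, and with shared arms joined 9 of 13 were higher and 2 lower. The family of miR-99, miR-100, miR-125 and miR-10 had 10 higher and 0 lower of 11, with 10 adjusted over the list alone, and upper quartile scaling gave 7 higher and 1 lower, and joined arms 9 and 0. In that family miR-125a-3p rose from 38.6 ± 11.02 to 246 ± 75.4 CPM (SD, n = 3). The cluster of miR-221 and miR-222 had 3 higher and 0 lower of 4, again 3 adjusted over the list alone, and 1 in each direction with upper quartile scaling. miR-222-3p rose 8.29-fold (edgeR adjusted p = 2.81e-05) and miR-221-3p 1.87-fold, and the second call was lost with upper quartile scaling. The miR-30 family had 3 higher and 1 lower of 8, the same adjusted over the list alone and 2 and 1 with upper quartile scaling, with miR-30d-5p 3.15-fold higher and miR-30b-5p 26.8-fold lower at 4.60 ± 3.997 CPM in high glucose (SD, n = 3).

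Other families went both ways. The miR-17~92 and paralog clusters had 4 higher and 4 lower of 11, the same adjusted over the list alone, and 2 and 5 with upper quartile scaling: miR-20a-5p and miR-19b-3p, which was 9.02-fold lower, against miR-25-3p, which was 1.63-fold higher and lost its call with upper quartile scaling. The cluster of miR-322 and miR-503 had 5 higher and 4 lower of 10, the same adjusted over the list alone and 3 and 4 with upper quartile scaling, with miR-351-5p 6.45-fold higher. The miR-23/24/27 clusters had 2 higher and 4 lower of 9, the same adjusted over the list alone and 1 and 5 with upper quartile scaling, with miR-24-3p 1.74-fold lower, a call lost without low glucose replicate 1 or 2, and miR-23b-5p 5.17-fold higher. miR-27b-3p, the other abundant member, had a log2 fold change of 0.11 (edgeR adjusted p = 0.515), which became -0.47 with upper quartile scaling and 2.47 when only its most abundant sequence was counted. The family of miR-15, miR-16, miR-195 and miR-497 had 2 higher and 2 lower of 6, the same adjusted over the list alone and 1 and 2 with upper quartile scaling, and miR-15b-5p was 4.94-fold lower. Among the higher members, miR-195-3p had only 2 counts in total in the low glucose libraries. The family of miR-148 and miR-152 had 1 of 4 in each direction, adjusted over the list alone as well, and 0 and 2 with upper quartile scaling, with miR-152-3p 1.97-fold lower. The family of miR-34 and miR-449 also had 1 in each direction of 6, and 0 higher and 1 lower both adjusted over the list alone and with upper quartile scaling, with miR-34c-5p 1.61-fold lower, a call lost without low glucose replicate 1 or 2. In the miR-29 family 1 of 3 was higher, and 0 adjusted over the list alone, while every other scaling gave 0 higher and 1 lower. The higher member, miR-29b-3p, shared 72.7% of its counts with another miRNA and is uncertain, and its call was lost without low glucose replicate 2 or 3 and when it was joined with miR-29c-3p. It was also lost with the filter of a mean CPM of 10 or more. miR-29a-3p had a log2 fold change of -0.33 (edgeR adjusted p = 0.0696), and 1.13 when only its most abundant sequence was counted. The Dlk1-Dio3 imprinted cluster had 2 higher and 1 lower of 4, the same adjusted over the list alone and with upper quartile scaling, among them miR-412-5p, for which 0% of the counts matched without a mismatch.

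**Figure D3:**
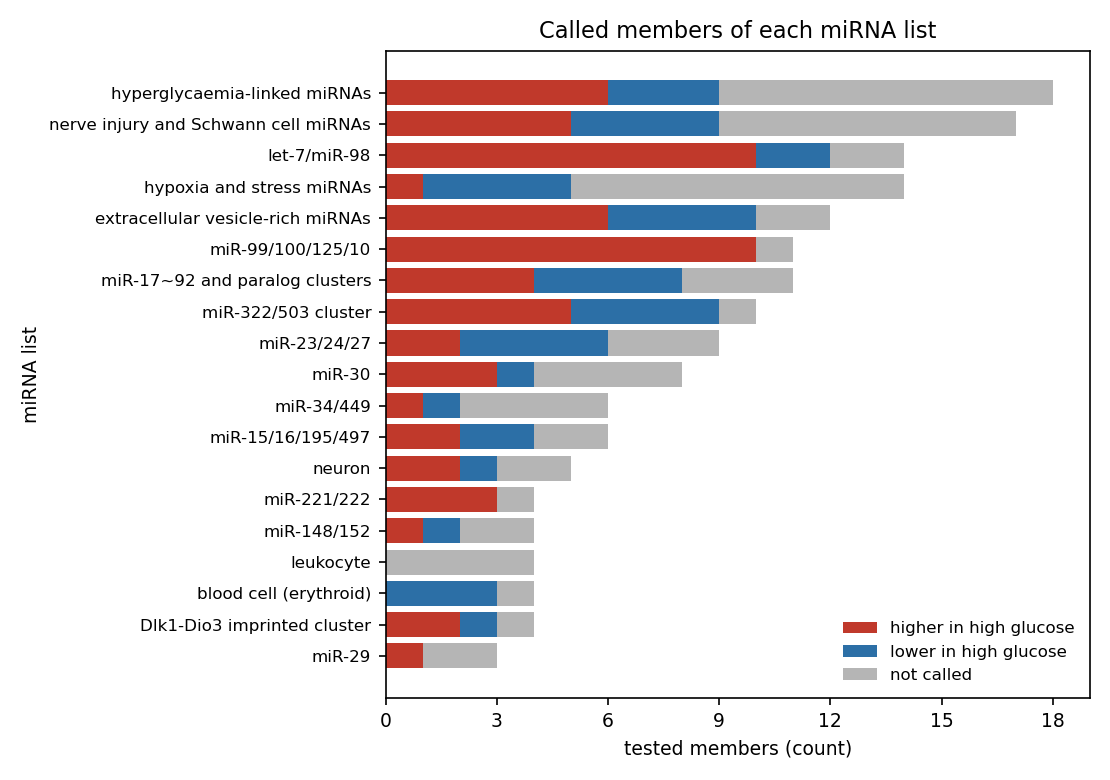
Number of tested members (horizontal) of each of the 19 miRNA lists (vertical) that were higher in high glucose (red), lower (blue) or not called (grey). The bars of the let-7 family and of the family of miR-99 and miR-10 each hold 10 higher members, which become 9 and 7 with upper quartile scaling, and the erythroid bar holds 3 lower members of 4.

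For miRNAs linked to Schwann cells and nerve injury, 5 of 17 tested were higher and 4 lower, the same adjusted over the list alone, and 3 were higher and 10 lower with upper quartile scaling. miR-222-3p rose and miR-21-5p fell, and miR-195-3p, with 341 counts in the high and 2 in the low glucose libraries, gave a ratio of 20.2 with a 95% counting interval of 5.55 to 168. Of the miRNAs linked to hyperglycaemia, 6 of 18 were higher and 3 lower, the same adjusted over the list alone, against 3 and 8 with upper quartile scaling. The abundant miR-320-3p had a log2 fold change of -0.04 (edgeR adjusted p = 0.877). Of the miRNAs linked to hypoxia and stress, 1 of 14 was higher and 4 lower, and 0 and 2 adjusted over the list alone, against 0 and 8 with upper quartile scaling. There miR-146b-5p and miR-34c-5p were lower, miR-34b-3p was higher at 132 ± 22.9 against 32.8 ± 28.7 CPM (SD, n = 3) but not without high glucose replicate 2, and miR-22-3p had a log2 fold change of -0.26 (edgeR adjusted p = 0.213). Of the miRNAs rich in extracellular vesicles, 6 of 12 were higher and 4 lower, the same adjusted over the list alone, against 5 and 5 with upper quartile scaling, with miR-423-5p 2.10-fold higher, a call lost with upper quartile scaling, and miR-484-3p higher at 252 ± 94.5 against 11.2 ± 19.3 CPM (SD, n = 3).

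Markers of other cell types were measured for the RNA that a culture could hold besides that of Schwann cells. Of the erythroid miRNAs, 0 of 4 were higher and 3 lower, the same adjusted over the list alone. These were miR-451-5p, miR-486-5p at 547 ± 87.9 against 1717 ± 583 CPM, and miR-16-5p at 131 ± 32.4 against 389 ± 122.1 CPM in high and low glucose (SD, n = 3). Of the neuronal miRNAs, 2 of 5 were higher and 1 lower, the same adjusted over the list alone, against 2 and 3 with upper quartile scaling. miR-128-3p was 9.20-fold higher, at 18246 ± 3423 against 1992 ± 983 CPM (SD, n = 3), and miR-218a-5p lower. Of the leukocyte miRNAs 0 of 4 were called in either direction by edgeR, and 0 adjusted over the list alone, against 1 lower with upper quartile scaling. The abundant one, miR-146a-5p, had a log2 fold change of -0.31 (edgeR adjusted p = 0.153), and 0.85 when only its most abundant sequence was counted. In the smaller lists, the liver miRNAs miR-122-5p and miR-192-5p were 3.48-fold and 3.22-fold higher in high glucose, and the retinal list had miR-183-5p at 18.7 ± 3.29 CPM in high and 59.3 ± 27.8 CPM in low glucose (SD, n = 3).

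Each list was also compared as a set with the other tested miRNAs, and camera, with a preset correlation of 0.01, called 0 of the 19 lists. The lowest adjusted p was 0.0819, shared by the erythroid list and the hypoxia and stress list, both toward lower values, and the family of miR-99, miR-100, miR-125 and miR-10, toward higher values. With an estimated correlation camera called 0 as well, with adjusted p of 0.541 for the erythroid and the hypoxia lists and 0.685 for the family of miR-99 and miR-10. At an unadjusted p under 0.05 camera had 4 lists, those 3 and let-7/miR-98, and fry, which does not compare a list with other miRNAs, called 9. Without high glucose replicate 1 camera called 1 list, the family of miR-99 and miR-10, and without low glucose replicate 2 it called 1, the erythroid list. The median and the mean log2 fold change differed in sign for the nerve injury list (-0.33 and 0.12), the miR-17~92 clusters (-0.55 and 0.35), the hyperglycaemia list (-0.11 and 0.51) and the cluster of miR-322 and miR-503 (-0.02 and 1.67). Camera pointed down for these 4, and also for the vesicle, miR-23/24/27 and neuronal lists, whose medians and means were above 0. Camera compares a list with the other tested miRNAs, and the median log2 fold change of all tested miRNAs was 0.68. The medians of all these lists were below that value, so a list can point down with a median above 0.

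The low glucose libraries held more of their counts in the 10 most abundant miRNAs, a difference that rests on miR-21-5p. The 10 most abundant miRNAs, miR-21-5p at their head, held 72.3% ± 1.19 of the counts in low and 63.2% ± 1.27 in high glucose (SD, n = 3), a difference of -9.10 percentage points. miR-21-5p alone held 43.7% ± 1.88 in low and 16.5% ± 3.33 in high glucose (SD, n = 3), a difference of -27.2 percentage points. The rest of the 10 together therefore held a larger share in high glucose. At equal depth, with 114497 listed reads per library, 372 ± 7.76 miRNAs were detected in high and 284 ± 7.89 in low glucose (SD, n = 3). The reads left for miRNAs other than miR-21-5p were not equal, being fewer in low glucose. Both the concentration and the detection differed with no overlap between the groups (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 libraries can give). With 5 or more counts required, the difference in detected miRNAs was 25.6 in place of 87.8. Sequences of 21 to 23 nt, the size of mature miRNAs, made up 78.4% ± 2.97 of the reads in high and 82.3% ± 1.52 in low glucose (SD, n = 3). The difference was -3.93 percentage points, with overlapping groups (exact two-sided permutation p = 0.2, where 0.1 is the smallest possible).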

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

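The tests of GC content, of the outside RNA for miR-451-5p and miR-122-5p, of a cell line variant and of added 3′ A, the fit of thinned counts with no filter, the criteria for depth and abundance, and the spread allowed beyond the bound for miR-486-5p and miR-16-5p were chosen after the results were seen, and the added columns below were looked at after the main comparison.

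The number in each sequence's name gives a bound on the reads left out of the file, if it ranks all sequences of a library by their reads; listed reads never rose with it, but the unlisted sequences were not seen. Under that assumption the listed reads were at most 28.0% ± 5.01 of the reads in high and at most 9.91% ± 0.457 in the low glucose controls, of at least 4284960 ± 161697 and 1295172 ± 113188 reads (SD, n = 3). Both shares are upper bounds, so they do not show in which group the listed share was larger. An added base is counted here as a last base that does not match the hairpin. Read errors at that base are included, and an added base that matches the hairpin is missed. A U added in this sense at the 3′ end was another column outside the comparison. It made up 3.40% ± 0.156 of annotated miRNA counts in high and 2.53% ± 0.126 in low glucose (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). miR-21-5p, with an added U on 0.139% of its counts in high and 0.141% in low glucose, held 16.5% and 43.7% of all counts. The pooled difference thus mixes the smaller share of miR-21-5p in high glucose with any change within single miRNAs. It does not show that U was added more often to a given miRNA.

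The first pattern is that 190 of the 297 tested miRNAs differed, between groups whose depth differed 9.31-fold; for the 130 calls that thinning to the smallest library left tested the tables argue against depth as the whole cause, since 120 of them, 92.3%, stayed called in the same direction. In a fit with no filter the other 60 kept their direction at a median of 0.905 of their log2 fold change (quartiles 0.652 and 1.03), but 30 of them, or 50%, lost the call, as their median log2 change went from 2.81 to 2.54 in size and the median SE from 0.943 to 1.497, and since 31 of the 60 had 0 thinned counts in a group and the median counts were 4.5 in high and 1 in low glucose, depth and an effect of glucose cannot be told apart for these 60. The tables argue also against miR-21-5p and other abundant miRNAs (95.6% of the 183 still tested stayed with the 5 most abundant left out) and against GC content (86.3% stayed with each library's GC trend removed), although across the 297 miRNAs the fold change rose with GC content (Spearman's rho 0.23, Pearson's r 0.14, permutation p = 7e-05 for rho; miRNAs are not independent replicates). Only 1 of the 10 splits of the 6 libraries, the real one, gave 190 calls and the highest other split gave 0, and 10 splits are too few for a share under 0.05; for the lists the real split gave 0 and the highest other 3, and any split reaches 0 (10 of 10), so that comparison decides nothing. The effect of glucose and a difference in RNA input or preparation between the groups stay open, the latter not tested.

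The second pattern links miR-451-5p to a form of miR-151-3p with an internal mismatch at hairpin position 60. The mismatched form made up 48.4% ± 6.19 of miR-151-3p in low glucose and 0.454% ± 0.0299 in high glucose (SD, n = 3), a 107-fold difference in share that argues against a sequence variant of the cell line, which both groups would carry alike. Its reads per library were 42.3 ± 7.51 in low and 56.7 ± 19.6 in high glucose (SD, n = 3), and miR-451-5p had 349 ± 80.1 and 355 ± 20.6 counts, against 224 ± 37.9 and 624 ± 149 for miR-486-5p and 54.0 ± 23.3 and 149 ± 43.5 for miR-16-5p, which were less constant. All miR-151-3p counts were 77, 83 and 103 in low and 8045, 13115 and 16392 in high glucose, so the difference in share rests mostly on the matching form. In high glucose the mismatched reads, 38, 55 and 77, rose with these counts. They therefore need not be a constant amount there. Reads of miR-451-5p per mismatched read differed by a factor of 0.758 between high and low glucose, which restates the near-equal reads that were seen first and decides nothing. For miR-486-5p and for miR-16-5p, which most cells make, the factors were 2.09 and 2.06 with no overlap between the groups (exact two-sided permutation p = 0.1 for each). Both lay above 2, the bound past which a factor was to count against outside RNA, but by less than their spread. These factors cannot decide it either. The mismatched form was 0.472%, 0.419% and 0.470% of miR-151-3p in the high glucose libraries. Its reads there followed the matching form, so dividing by them does not compare with a constant outside amount. The factor was 3.175 for miR-363-3p, at 6.67 ± 1.53 counts in low and 28.3 ± 21.2 in high glucose, with overlapping groups (SD, n = 3; exact two-sided permutation p = 0.2). For the abundant miR-21-5p it was 2.59 with no overlap. A near-constant amount of RNA from outside the cells, such as that in serum, is a candidate explanation only. It and an effect of glucose cannot be told apart for miR-451-5p, miR-486-5p and miR-16-5p.

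The third pattern is that the liver miRNA miR-122-5p was higher in high glucose and ended differently. A 3′ A was added to 22.7% ± 1.03 of its counts in low and 1.43% ± 0.365 in high glucose (SD, n = 3), and its exact 21 nt form made up 48.9% ± 3.23 and 85.9% ± 2.40. A near-constant amount of outside RNA would give like counts in both groups if the reads per amount of RNA were alike. That assumption was not tested. miR-122-5p had 464 ± 17.2 counts in low and 14197 ± 5248 in high glucose (SD, n = 3). Its reads per mismatched miR-151-3p read, 22.9 times as many in high glucose, mainly restate these counts. Under that assumption alone, the tables argue against such a constant amount as its source, but not against outside RNA that differs between the groups. They argue also against a loss of added A from all miRNAs, since the median change over the 57 other miRNAs with enough counts was -0.15 percentage points (quartiles -1.42 and 0.67) against -21.3 for miR-122-5p, but other ends changed too: the share with an added A fell from 28.8% ± 2.68 in low to 15.8% ± 1.51 in high glucose for miR-486-5p, whose added U rose from 6.55% ± 2.57 to 21.6% ± 2.16 (SD, n = 3), and added A rose by 14.98, 13.7 and 13.4 percentage points for miR-20a-5p, miR-191a-5p and miR-27a-3p. A change of miR-122-5p in the cells with glucose and another source of it in the high glucose cultures stay open, and neither was tested.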

How the results depend on the processing

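All alternatives were planned except annotated hairpins only, exact alignments only, the GC correction and joined arms, which were chosen after the data were seen. The count of higher miRNAs, 123, ranged from 79 (without high glucose replicate 2, with 203 miRNAs tested) to 117 in the fits without a library, and was 66 with thinned counts and 78 with annotated hairpins only, each with fewer miRNAs tested. The count of lower miRNAs, 67, ranged from 41 (without low glucose replicate 2) to 59 without a library, and was 40 with only the most abundant sequence of each miRNA. Under the other alternatives both counts stayed within 1.5 times. The lists called, 0, ranged from 0 to 1 without a library, and fry called 9. The differences between groups in the 10 most abundant miRNAs (-9.74 to -8.47 percentage points), detection (84.7 to 92.4 miRNAs) and 21 to 23 nt share (-5.49 to -2.53 percentage points) kept their sign in every fit without a library, in designs that cannot reach 0.05.

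Of the log2 fold changes of named miRNAs under the alternatives, 1276 kept direction and side of the threshold, 76 lost the call, 27 gained it and 5 turned: miR-99a-5p to -0.14 and miR-27b-3p to -0.47 with upper quartile scaling, and miR-146b-5p to 0.078, miR-146a-5p to 0.85 and miR-29a-3p to 1.13 with the most abundant sequence only; the cause was not tested. Of 57 called named miRNAs, 46 kept the call in every fit without a library that tested them; miR-146b-5p lost it in 5, and miR-99a-5p, miR-322-3p and miR-455-5p in 4. The replicate block gave 104 higher and 58 lower miRNAs, all 162 among the 190. Pairing by number was not apparent: deviations of same-numbered libraries correlated at 0.05, -0.02 and -0.23 across miRNAs, which are not independent replicates. With 3 libraries in a group this cannot exclude that same-numbered libraries were paired. Median log2 shifts over 0.1 came with DESeq2's size factors (-0.13), library totals (-0.12), upper quartile (-0.58), DESeq2's test (-0.13), thinning (-0.20), the most abundant sequence only (0.13) and the fit without low glucose replicate 2 (0.16). Depth limits the fold changes of the 49 higher miRNAs with a low glucose mean of 3 or fewer counts.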

Other observations

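The tests of arm ratios and added ends, and the choice of the miRNAs named here, were made after the data were seen.

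Among 40 annotated hairpins with both arms tested, the ratio of 5p to 3p differed between the groups in 15 by limma's moderated test with Benjamini-Hochberg adjustment, higher in high glucose in 3 and lower in 12, and in 5 the arms were called in opposite directions. In 7 of the 15, 6 of them lower, an arm had a mean of 3 or fewer counts in low glucose, so that the size of its ratio rests on the prior count and on sequences too rare to be listed. Of the other 8, 2 were higher and 6 lower, and of the 5 opposite calls only that of miR-106b had more counts in both arms. miR-106b-5p fell from 169 ± 41.4 to 59.5 ± 18.8 CPM while miR-106b-3p rose from 480 ± 3.94 to 799 ± 56.8 CPM (SD, n = 3). miR-23b-5p, with a mean of 2 counts in low glucose, rose from 15.1 ± 2.47 to 77.7 ± 32.3 CPM while miR-23b-3p fell from 604 ± 94.96 to 228 ± 101 CPM (SD, n = 3). For miR-872, miR-450b and miR-503 the 5p arm fell and the 3p arm rose, and for the first 2 the 3p arm was listed at 0 in low glucose. In miR-99b both arms rose, with a log2 5p to 3p ratio higher by 1.42 (SE 0.35, limma adjusted p = 0.0228).

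The predicted hairpins took 10.7% ± 1.72 of the counts in low and 5.40% ± 1.72 in high glucose (SD, n = 3; exact two-sided permutation p = 0.1). This rests on the hairpin numbered 34122 on chromosome 7, which alone held 8.16% ± 1.28 in low and 0.9999% ± 0.292 in high glucose; without it the share was 2.50% ± 0.435 in low and 4.397% ± 1.43 in high glucose, with overlapping groups (SD, n = 3; exact two-sided permutation p = 0.2). In the other lists too small to test, the called members fell: in the miR-181 family miR-181a-5p fell by 1.56 on the log2 scale and miR-181b-5p fell by 0.81, in the miR-26 family miR-26b-5p fell by 0.51 and miR-26a-5p had a value of -0.30 (edgeR adjusted p = 0.112). The muscle miRNA miR-499-5p fell by 1.25 and miR-199a-3p of the fibroblast and smooth muscle list fell by 1.16, with miR-143-3p at -0.23 (edgeR adjusted p = 0.414). The endothelial miR-126a-3p, pancreatic miR-375-3p and oligodendrocyte miR-219a-3p had log2 fold changes of -0.18, 0.75 and 0.68 (edgeR adjusted p = 0.858, 0.639 and 0.529), and the epithelial list had 0 tested members.

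Of 58 miRNAs with 100 or more counts in every library, the share with an added 3′ A was higher in high glucose with no overlap in 9 and lower in 15, and the share with an added U higher in 10 and lower in 5, where chance separates 10% either way. Those 10 include let-7c-5p and miR-128-3p, at 0.0206% and 0.0688% in high against 0% in low glucose. Such rare forms can go unlisted in the low glucose libraries through their lower depth alone. Of 6 internal mismatch sites with a share of 20% or more in a library, miR-193a-5p had another that differed with no overlap, at 74.3% ± 16.9 of its counts in low and 24.8% ± 3.72 in high glucose (SD, n = 3; exact two-sided permutation p = 0.1). These shares rest on few reads: 11, 11 and 22 of 15, 19 and 24 in low, and 8, 15 and 21 of 30, 73 and 77 in high glucose. miR-184-3p, like miR-451-5p, had near-equal raw counts in both groups, 516 ± 22.1 in low and 540 ± 166 in high glucose (SD, n = 3).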
